A study of Arabidopsis thaliana with 78 samples.

How the data were processed

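RNA of whole Arabidopsis thaliana seedlings, 7 days old, was measured on 78 one-colour Agilent arrays. Seedlings were held without oxygen in the dark and returned to air. The labels give 24 groups. Col-0, the wild type, was given 8 h of anoxia (4 arrays per group). Col-0, ein2-5 and ein3eil1 were given 4 h (3 arrays per group). Each of these 4 arms has 6 times: untreated, the end of anoxia, and 0.5, 1, 3 and 6 h of air. The series text speaks of independent experiments at each time, so arrays were treated as independent. P-values here measure differences against a spread between arrays that is pooled for each gene over all 24 groups. This spread can be smaller or larger than that of the groups compared. Arrays with the same replicate number correlated, as given below, which the main model does not use.

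Per the file headers, each array file holds the intensity of every spot as read by Agilent Feature Extraction 10.7.1.1, already corrected for background and for trends across the slide. The deposited matrix holds log2 values, which equal the log2 processed signal minus the 75th percentile of the array. Recomputing that step from the scanner files gave a correlation of 1 on every array and a median difference of at most 0.0028. The authors did not state further steps. Each array had 43803 spots that were not controls, for 43603 probes. The software's non-uniformity and population outlier flags removed 884 spots over all arrays, and 0 spots were saturated. The 75th percentile of the raw signal ranged from 364.9 to 1987.7 between arrays, and 64% to 78.8% of probes were well above background. For 15 arrays the software's own quality note read "Evaluate". The number of arrays limits the precision.

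Probes were joined to genes of the TAIR10.1 annotation by accession. Of 35137 names on the array, 26309 were matched, which gave 34358 probes for 25433 genes. The other 9245 probes had no gene in that annotation and took no part in the gene tests. Where a gene had more than 1 probe (6940 genes), the probe with the highest mean stood for it. Among genes called after 4 h of anoxia, 690 had another measured probe, of which 59 had the opposite sign and 13 differed by over 2-fold in the opposite direction. After 8 h these numbers were 1166, 124 and 29, and LHCB2.1 was among the last. Missing from the array by accession were HSFB1, DHAR1, TCH3, BZIP1 and ACT2.

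Levels were log2 processed signals minus the 75th percentile of the array. A single limma model (limma 3.58.1, R 4.3.3) of 24 group means over the 78 arrays gave 28 comparisons. Tested genes were well above background on every array of at least 1 compared group. P-values were adjusted by Benjamini-Hochberg within each comparison. A gene was called at an adjusted p under 0.05 with a change of at least 2-fold, and only called genes are said to rise, fall or change. The comparisons were each arm's response to anoxia, the change from the end of anoxia to each time in air in Col-0, 6 h of air against untreated Col-0, both mutants against untreated Col-0, and interactions. The interactions set 8 h against 4 h of anoxia, and each mutant's change from the end of anoxia against that of Col-0. Values are given with the standard error (SE) of the model unless an SD is named, and n is 4 arrays per group at 8 h and 3 at 4 h.

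These choices, the gene lists and the rule for naming genes were fixed before the data were examined. Named were, per comparison, the 6 largest rises and 6 largest falls among called genes with a symbol, with arrays that did not overlap where 2 groups were compared. Also named were the 4 called members of each list with the largest change, or its 2 largest if none was called. A panel of 22 genes completed the rule, namely ADH1, PDC1, SUS1, SUS4, LBD41, HRE1, HRE2, PCO1, PCO2, HB1, EIN2, EIN3, EIL1, EBF2, ETR2, ERF1, ACS2, ACO1 (AT2G19590), HSFA2, ZAT12, RBOHD and JAZ1. The text gives a selection of them. Where a group was above background on none of its arrays, a fold is given as a bound. The bound is the mean of the bright group against the mean, over the dim group, of the higher of each array's lowest well-above-background signal and the probe's own signal.

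The 16 gene lists were hypoxia response (44 genes), fermentation and glycolysis (21), heat shock and chaperones (25), oxidative stress (27), ethylene synthesis and signalling (24), ethylene response factors and markers (21), jasmonate (26), abscisic acid, dehydration and cold (25), defence, touch and wounding (25), photosynthesis (26), circadian clock (16), darkness and starvation (13), cell cycle (16), auxin and expansion (14), root cell types (12) and reference genes (6). Each was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, which gave 448 list tests, adjusted within each comparison. Of 199 calls at the preset correlation, 26 held with the estimated one. Beside each count over all genes stands, where it differs, the count adjusted over the list alone. Some genes belong to more than 1 list. The genes called higher or lower in Col-0 after 8 h of anoxia, or after 1 h of air that followed it, formed 4 response sets. They were followed in the 4 h arrays, which had no part in choosing them.

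Whether equal replicate numbers pair arrays was checked by correlating each array's deviations from its group mean. Arrays with the same number correlated on average at 0.28 in the 4 h arms, against -0.14 for other numbers, and at 0.17 against -0.05 in the 8 h arm. Every pair correlated above 0.1 in 8 comparisons: Col-0 4 h anoxia, its 4 times in air, 0.5 h of air and 6 h of air against untreated after 8 h, and anoxia in ein2-5. A replicate block changed no call count there by over 1.5 times. Arrays lay on 21 slides scanned in 10 batches, and directions were checked within each slide or batch that held both groups.

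The procedure was tested on simulated arrays with normal noise of each gene's estimated variance. This noise was independent between genes and arrays, without the correlation within slides, replicate numbers and gene sets of the real data. The rates may therefore not hold for the real arrays. Changes of log2 1.5 and 3 were called for 80% and 100% of altered genes in Col-0 after 4 h of anoxia, for 96% and 100% after 8 h, and for 59% and 91% in the interaction of ein2-5 at 6 h of air.

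Alternatives were normexp background subtraction with an offset of 50, quantile normalization, median centring, the deposited matrix, no filter and a strict filter on dim probes, the mean over probes, only the compared arrays, a replicate block, slides as a fixed block, leaving out each array in turn and the estimated correlation. The normexp alternative had been planned on mean spot signals, but the files give only median signals, which were used. Added after the data were seen were a gene-length covariate, leaving out 8 arrays with an extreme gene-length trend, slides as a random block, and the ethylene synthesis and signalling list without the genes mutated in each line. Chromosome positions were not used in the report.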

Results

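Transcript levels of whole 7-day-old Arabidopsis seedlings were measured before anoxia, at its end, and after 0.5, 1, 3 and 6 h of air. The 78 arrays fall into 24 groups. Col-0 with 8 h of anoxia had 4 arrays at each time, and Col-0, ein2-5 and ein3eil1 with 4 h of anoxia had 3. The ein2-5 line carries a lesion in EIN2, a membrane protein of ethylene signalling, and ein3eil1 lacks the transcription factors EIN3 and EIL1 that act after it. Raw 75th percentile signals ran from 364.9 to 1987.7, and 64% to 78.8% of probes were well above background on an array. The number of arrays limits the precision. Untreated seedlings were taken before anoxia, and anoxia and re-aeration took place in the dark, so darkness and the hour of harvest changed together with anoxia and time in air.

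Untreated arrays differed in their clock genes. On replicate 1 of the untreated 8 h Col-0 group the evening gene PRR5 stood at a log2 level of 0.85, against a mean of -2.76 on the other 3 arrays. LHY, a morning gene, was lower there by a log2 difference of -5.92. The deviation of 6 evening genes minus that of 3 morning genes was 6.91 on this array. It was 6.53 and -5.60 on replicates 3 and 1 of untreated ein2-5, and 6.08 and -5.82 on replicates 3 and 1 of untreated ein3eil1.

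The end of 4 h of anoxia was compared with untreated Col-0 to find the transcripts that change without oxygen. ADH1 and PDC1, the alcohol dehydrogenase and pyruvate decarboxylase of ethanol fermentation, rose 133-fold (log2 7.06 ± 0.36, adjusted p = 3.7e-23) and 172-fold (7.43 ± 0.41, n = 3 arrays per group). Of 43 measured genes of the hypoxia response, 41 rose and 1 fell. The largest rises were those of AT5G10040, at least 2180-fold, and of the aquaporin gene NIP2;1, at least 659-fold. The transcription factor genes HRE2 (6.44 ± 0.50) and LBD41 (4.28 ± 0.55), the cysteine oxidase genes PCO1 (4.75 ± 0.38) and PCO2, and the phytoglobin gene HB1 (4.42 ± 0.40) were among them. The list's adjusted p was 2.27e-66, and 1.03e-05 with an estimated correlation. Among 21 genes of fermentation and glycolysis 11 rose, with the sucrose synthase genes SUS4 67.2-fold and SUS1 by 4.03 ± 0.29 on the log2 scale (adjusted p = 0.0188 with an estimated correlation).

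Chaperone genes rose with them after 4 h of anoxia. Of 22 measured members of the heat shock list 15 rose (17 adjusted over the list alone), among them HSP17.6A, at least 16.6-fold, and HSP23.6-MITO, at least 10.2-fold (adjusted p = 0.127 with an estimated correlation). In the darkness and starvation list 9 of 12 genes rose (10 adjusted over the list alone), DIN2 by 4.33 ± 0.78 and SEN1 by 4.19 ± 0.82 (adjusted p = 0.194 with an estimated correlation). ZAT12 and RBOHD, a zinc finger gene and an NADPH oxidase gene of stress signalling, rose by 3.45 ± 0.46 and 2.86 ± 0.29. Within the defence, touch and wounding list 10 of 23 rose and 2 fell (adjusted p = 0.299 with an estimated correlation), and 9 of 21 ethylene response factors and markers rose (0.324). In ethylene synthesis and signalling the receptor gene ETR2 (2.41 ± 0.29) and the ACC oxidase gene ACO1 (2.69 ± 0.23) rose. ACS6 of that list was lower (-1.09 ± 0.32), a call lost when either of 2 single arrays was left out. The other panel members EBF2 (0.51), ACS2 (0.46), EIN2 (-0.37), EIN3 (0.10) and EIL1 (0.02) were not called.

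RSL4, a transcription factor of root hair growth, fell by 3.75 ± 0.48 on the log2 scale after 4 h of anoxia, EXPA7 by 3.44 ± 0.70, EXPA18 by 3.28 ± 0.62 and COBL9 by 2.87 ± 0.47. Of 12 root cell type markers 4 fell (adjusted p = 0.299 with an estimated correlation). The other lists gave smaller counts, with 4 of 25 oxidative stress genes, 3 of 26 jasmonate genes and 2 of 24 genes of abscisic acid, dehydration and cold called higher. The jasmonate gene JAZ4 (-2.13) and the abscisic acid gene NCED3 (-1.35) were called lower, the latter not when either of 2 single arrays was left out. The cell cycle list had 2 of 16 lower, auxin and expansion 4 of 14 lower and 1 higher, and the clock 0 of 16 called by limma. The cell cycle genes CDT1A and CYCB1;2 and the auxin gene IAA29 each lost their call when any of 3 single arrays was left out. EXPA8 lost its call with either of 2. Of 26 photosynthesis genes 2 were called higher (0 adjusted over the list alone) with a median of 0.75, and the list call was lost with quantile normalization (adjusted p = 0.643). None of 5 reference genes was called, although AT2G28390 stood at -0.70 with an adjusted p of 2.92e-06.

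In all, 864 genes rose and 1946 fell of 19923 tested after 4 h of anoxia. Of the 2810, 2767 had arrays that did not overlap between the groups, a share raised by calling the genes on these arrays. Among genes not chosen in this way chance gives 10%, which is no chance value for called genes. Median centring moved the median change of tested genes from -0.07 to 0.07 and the share of called genes that rose from 30.7% to 41.7%. Within the 2 slides that held both groups, 99.9% and 100% of called genes had the same direction. Here and below, the genes were called on a fit that includes the arrays of each slide or batch, which raises such shares.

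After 8 h of anoxia, compared in the same way with untreated seedlings, all 42 measured genes of the hypoxia list rose (adjusted p = 0.000504 with an estimated correlation). PDC1 rose 231-fold (log2 7.85 ± 0.36, n = 4 arrays per group), HRE2 155-fold (7.28 ± 0.43), ADH1 105-fold (6.72 ± 0.31) and CML38, a calmodulin-like gene, 246-fold. All 24 measured heat shock and chaperone genes rose, HSP23.6-MITO at least 43.7-fold (adjusted p = 0.0978 with an estimated correlation). In fermentation and glycolysis 10 rose and 1 fell of 21 (0.101 with an estimated correlation). The defence, touch and wounding list had 13 of 24 higher and 2 lower (0.396), ethylene response factors and markers 11 of 21 higher (0.427), and darkness and starvation 8 of 12 higher (0.416). Transcription factor genes WRKY46 (4.33), WRKY22 (4.11) and ERF6 (3.73) were among the called members. Ethylene synthesis and signalling genes had a median of -0.11 but a mean of 0.31, with the test upward at an adjusted p of 0.34.

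Root cell type markers showed the largest falls after 8 h of anoxia, with 8 of 11 called lower (adjusted p = 0.0978 with an estimated correlation). EXPA18 was at least 27.3-fold lower, EXPA7 at least 27.4-fold lower, RHS12 at least 15.1-fold lower, and COBL9 fell by 5.51 ± 0.41. SCR, a regulator of the ground tissue, fell by 2.19. Of 26 photosynthesis genes 14 rose, LHCB3 by 1.31 ± 0.30. That list's call was lost with quantile normalization (adjusted p = 0.0553) and with an estimated correlation (0.443). In the clock list 2 of 16 rose, PRR5 by 4.06 ± 0.58 and PRR7 by 2.82, and LHY was called lower (-2.06, adjusted p = 0.0402; 0 lower adjusted over the list alone; lost with any of 6 arrays left out), against the untreated group in which replicate 1 stood apart. The reference gene AT2G28390 fell by 1.08 ± 0.10, a call lost with median centring, and UBQ10 stood at 1.04, a call lost with quantile normalization.

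The 8 h comparison called 1497 genes higher and 2665 lower of 18773 tested, and 4582 genes in all without replicate 1 of the untreated group. Arrays did not overlap for 3465 of the 4162, again a share raised by calling the genes on these arrays. Chance gives 2.86% only among genes not chosen in this way. On the 4 slides that held both groups 94.5% to 99.9% of called genes had the same direction. The 4 h and 8 h experiments, which share no arrays, called 669 genes higher in both, against 64.9 if the calls were independent, and 1494 lower in both, against 250.2. Only 7 genes were called in opposite directions, and changes correlated across genes at 0.85, genes not being independent replicates.

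**Figure D1:**
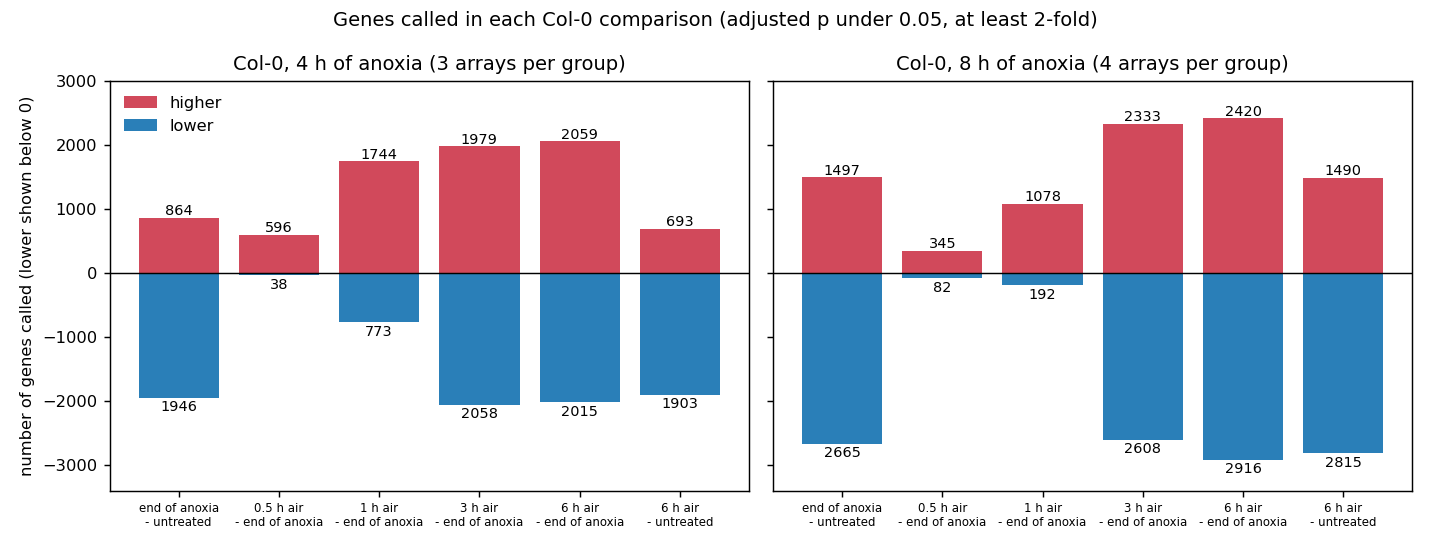
Bars give the number of genes called higher (above 0) and lower (below 0) in Col-0 by limma, for each comparison of the 4 h (n = 3 arrays per group) and 8 h (n = 4) experiments. The largest count is that of 6 h of air after 8 h of anoxia, with 2420 higher and 2916 lower, and the smallest that of 0.5 h of air after 8 h, with 345 and 82.

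Whether 8 h of anoxia changes transcripts differently from 4 h was asked of the difference between both responses. Auxin-related growth genes stood out: SAUR15 was higher by 3.69 ± 0.64, SAUR22 by 3.56 ± 0.72, SAUR23 by 4.01 ± 0.80, IAA5 by 4.17 ± 0.82 (adjusted p = 0.00434) and IAA1 by 2.33 ± 0.36. In the auxin and expansion list 3 of 14 genes were called higher (5 adjusted over the list alone), with a median difference of 0.70 (adjusted p = 0.0364 with an estimated correlation). The hypoxia list had 4 of 43 higher (10 adjusted over the list alone; adjusted p = 0.588 with an estimated correlation), while ADH1 (-0.34 ± 0.47) and PDC1 (0.42 ± 0.54) were not called. All 4 called members lost their calls when single arrays were left out, CML38, AT4G10270 and HRA1 with either of 2 and PCO1 with any of 8. CML38 stood at 5.49 at the end of 8 h and 5.75 at the end of 4 h, but at -2.46 and 0.97 ± 1.49 (SD) before. The cell wall gene PRP3 was lower by a log2 difference of -3.11 ± 0.62 and MOP10 by -3.04 ± 0.65. COBL9 (-2.64) lost its call when any of 5 single arrays was left out, and EXPA18, not above background at the end of 8 h of anoxia and so given no size, with any of 9. In all 2 of 12 root cell type markers were called lower (5 adjusted over the list alone; adjusted p = 0.0761 with an estimated correlation). SAUR19 lost its call without replicate 3 of the 4 h end of anoxia.

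Over all genes this difference called 72 higher and 64 lower. The count moved by over 1.5 times when any of 11 single arrays was left out, from 51 without replicate 1 of the untreated 4 h group to 439 without replicate 1 of the untreated 8 h group. Neither a slide nor a scanning batch held all 4 groups, and with slides as a fixed block 322 genes were called. Clock genes of untreated Col-0 differed between the experiments. LHY stood at -2.97, 3.46, 2.27 and 3.1 on the 8 h arrays and at -4.18, -2.07 and -3.84 on the 4 h arrays. SAUR15 stood at -2.92 and -1.89 in the untreated 8 h and 4 h groups, and at 0.31 and -2.35 at the end of anoxia. Length of anoxia and hour of harvest therefore cannot be told apart in this difference.

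The earliest change in air was asked at 0.5 h, each time against the end of anoxia. After 4 h of anoxia, RRTF1, a redox-responsive transcription factor gene, rose 405-fold (log2 8.66 ± 1.08, n = 3), and the small heat shock protein genes ATHSP22.0 and HSP21 rose 340-fold and 268-fold. RRTF1 levels at the end of anoxia were spread widely between arrays (mean -6.11, SD 3.01), so the size of its rise is uncertain. Of 24 heat shock and chaperone genes 23 rose, with a median of 4.28 (adjusted p = 3.8e-06 with an estimated correlation), and the heat shock factor gene HSFA2 rose by 6.48 ± 0.86. APX2, an ascorbate peroxidase gene, rose at least 62.2-fold and was among 8 of 26 oxidative stress genes called higher (adjusted p = 0.193 with an estimated correlation). In the list of abscisic acid, dehydration and cold, 6 of 24 rose (0.121), including CBF1 by 4.52 and DREB1A by 3.91. CBF4 and DDF1, of the same gene family, each rose by 7.44. The median of oxidative stress was only 0.02, and of abscisic acid, dehydration and cold 0.11, so the called members stood apart from the rest.

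At the same time after 8 h of anoxia 15 of 24 chaperones were called higher (17 adjusted over the list alone; adjusted p = 0.00686 with an estimated correlation), and the difference from 4 h was not tested. HSP21 started there from a level of -1.32 at the end of anoxia, against -4.64 after 4 h, and ATHSP22.0 from -1.78 against -5.94. HSFA2 rose by 3.72 ± 0.74, RRTF1 at least 118-fold, CBF4 at least 57.4-fold and DDF1 at least 29-fold (n = 4). The regulators ZAT10 (2.84), OXI1 (2.87) and ERF1 (2.73) rose as they had after 4 h (3.10, 3.48 and 2.85). None of the 42 hypoxia genes was called by limma after 8 h, with 2 of 43 higher after 4 h, and ADH1 (0.14) and PDC1 (-0.22) were not called. ABCI4 fell by 2.05 ± 0.26 after 4 h and 1.58 after 8 h. In the list of abscisic acid, dehydration and cold the median after 8 h was -0.03 but the mean 0.39 (adjusted p = 0.745 with an estimated correlation).

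At 0.5 h, 596 genes rose and 38 fell after 4 h of anoxia, and 345 rose and 82 fell after 8 h. Both experiments called 296 higher, against 10.5 if independent, and 0 in opposite directions. Called genes had the same direction for 99.8% to 100% within 3 slides at 4 h and 98.8% to 99.8% within 4 slides at 8 h.

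After 1 h of air jasmonate genes rose in both experiments, 17 of 26 after 4 h of anoxia and 16 of 25 after 8 h (adjusted p = 0.165 and 0.154 with an estimated correlation). JAZ7, a repressor of jasmonate responses, rose by 6.33 ± 1.09 (n = 3) and 5.68 ± 0.94 (n = 4). Its level at the end of 4 h of anoxia was spread widely between arrays (mean -4.38, SD 3.28). JAZ1 rose by 3.13 ± 0.45 and 3.51 ± 0.39, JAZ10 by 4.63 and 4.13, and CYP94C1, an enzyme that oxidises the jasmonate hormone, by 6.31 ± 0.69 and 5.03. The chaperone list had 23 of 24 higher each time, with 1 lower after 4 h (adjusted p = 0.00754 and 0.00468 with an estimated correlation). RRTF1 rose 599-fold (95% interval 139 to 2590) and at least 727-fold. Its levels at the end of 4 h of anoxia were spread widely between arrays (mean -6.11, SD 3.01). ERF1, a target of ethylene signalling, rose by 3.87 and 5.28 ± 0.48. In ein2-5 after 4 h of anoxia ERF1 went from -4.81 to 0.16, against -4.37 to -0.5 in Col-0 (difference 1.09 ± 0.79, not called). In the list of abscisic acid, dehydration and cold 8 of 24 and 7 of 23 rose (0.165 each), RD29A by 3.15 ± 0.41 after 4 h of anoxia. Auxin and expansion genes rose in 7 of 14 cases after 4 h, with 1 lower (0.118), with IAA5 at 6.26 ± 0.62, and in 4 of 13 after 8 h, with IAA5 at 2.42. Hypoxia genes began to fall, 13 of 43 with 3 higher after 4 h (0.576) and 7 of 42 with 2 higher after 8 h (0.592). SRO4 fell by 3.09 ± 0.57 and AT5G10040 by 2.04 after 4 h, while HRE2 rose by 2.43 and 1.89. The ethylene response factor list after 4 h had a median of -0.41 but a mean of 0.13.

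At 1 h, 1744 genes rose and 773 fell after 4 h of anoxia, and 1078 rose and 192 fell after 8 h. Both called 864 higher, against 92.4 if independent, and 4 in opposite directions. Within slides 99.7% to 99.9% of called genes had the same direction at 4 h and 99.2% to 99.8% at 8 h.

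The difference between both experiments at 1 h of air was tested directly. RD29A was lower after the longer anoxia by a log2 difference of -3.05 ± 0.54, and MYB4 was higher by 2.31 ± 0.38. RHS18 was called higher too, but was not above background at the end of 8 h of anoxia, so no size is given. IAA5 (-3.84 ± 0.82) and SAUR20 (-3.71) lost their calls without replicate 3 of the 4 h end of anoxia or without replicate 2 of 4 h at 1 h of air. The auxin and expansion list had 2 of 14 lower (6 adjusted over the list alone; adjusted p = 0.172 with an estimated correlation) and chaperones 3 of 24 lower (9 adjusted over the list alone; 0.305). Of these chaperones ATHSP22.0 lost its call when any of 5 single arrays was left out, and AT1G53540 and HSP17.4 with any of 8. Limma called 39 genes higher and 69 lower, a count that moved by over 1.5 times for 7 single arrays, from 17 without that replicate 2 to 174 without replicate 3 of the 8 h end of anoxia. With slides as a fixed block 487 genes were called. No slide or batch held all 4 groups.

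**Figure D2:**
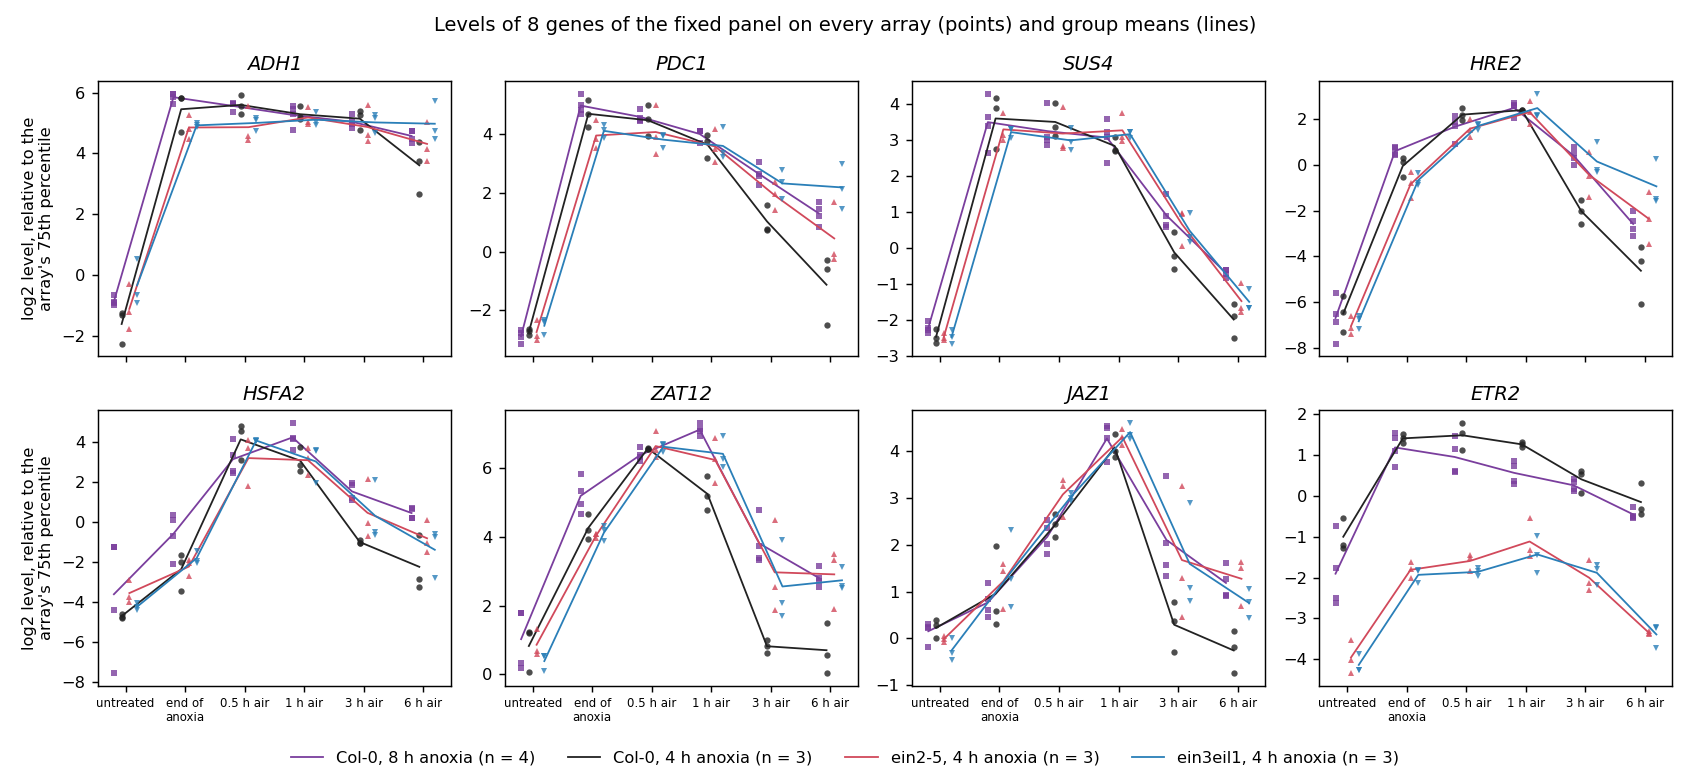
Points are log2 levels on single arrays, relative to the 75th percentile of the array, of ADH1, PDC1, SUS4, HRE2, HSFA2, ZAT12, JAZ1 and ETR2 at each time, and lines join group means of the 4 arms. ADH1 goes from -1.61 in untreated 4 h Col-0 to 5.45 at the end of anoxia and 3.61 after 6 h of air, and PDC1 from -2.74 to 4.69 and -1.13.

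After 3 h of air most hypoxia genes had fallen from the end of anoxia, 31 of 43 after 4 h of anoxia and 31 of 42 after 8 h (adjusted p = 0.102 and 0.416 with an estimated correlation). SUS4 fell by 3.73 ± 0.34 and 2.59 ± 0.30, PDC1 by 3.66 ± 0.41 and 2.33 ± 0.36, and RBOHD by 3.71 ± 0.29 and 2.39, whereas ADH1 was called after neither (-0.30 and -0.81). HSP21 stayed above the end of anoxia by 7.36 ± 0.61 and 5.61, and RD29A rose by 5.02 ± 0.41 and 4.54 ± 0.36. Jasmonate genes differed in count, with 1 of 25 higher and 3 lower after 4 h of anoxia and 16 of 26 higher after 8 h (0.515 with an estimated correlation). After 8 h LOX3 rose by 3.79 and CYP94C1 by 4.02, together with the ethylene response factor gene RAP2.6, 127-fold. The ethylene response factor list after 8 h had a median of -0.20 with an upward test (adjusted p = 0.933). The difference in jasmonate genes between experiments was not tested at 3 h. Of ethylene synthesis and signalling genes 7 of 22 rose each time, with 2 lower after 4 h and 3 after 8 h (0.42 and 0.416). ACO1 fell by 1.97 and 1.65, and the rises included those of the receptor gene ERS1 by 1.87 ± 0.25 after 4 h and EBF2, which targets EIN3 for degradation, by 1.32 ± 0.35 and 1.75. IAA29 rose by 4.49 ± 0.51 and 4.65.

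Photosynthesis genes fell at 3 h, 17 of 26 after 4 h of anoxia and 16 of 26 after 8 h (adjusted p = 0.456 and 0.669 with an estimated correlation). The antenna gene LHCB2.1 fell by 4.25 ± 0.62 after 4 h. Quantile normalization kept that list's call after 4 h (0.00158) and ended it after 8 h (0.228). Most single light-harvesting genes called lower after 4 h were, however, no longer called with quantile normalization. Cell cycle genes fell as well, 9 of 16 and 11 of 16 (0.422 and 0.416 with an estimated correlation), KNOLLE by 1.75 after 8 h. Defence, touch and wounding genes fell in 13 of 23 and 7 of 24 cases, with 2 and 1 higher, among them PAD3 by 3.17 after 4 h (13 and 6 adjusted over the list alone; 0.422 and 0.669).

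At 3 h, 1979 genes rose and 2058 fell after 4 h of anoxia, and 2333 rose and 2608 fell after 8 h. Both called 1265 higher and 1347 lower, against 225.7 and 271.4 if independent, and 12 oppositely. Quantile normalization moved the 8 h median from -0.13 to -0.01 and the share called higher from 47.2% to 57.7%. No slide held both groups, and within the scanning batches that did, 100% of called genes had the same direction.

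After 6 h of air 38 of 43 hypoxia genes had fallen from the end of 4 h of anoxia (adjusted p = 0.00754 with an estimated correlation) and 35 of 42 from the end of 8 h (0.188). PDC1 fell by 5.82 ± 0.41 and 3.67 ± 0.36, SUS4 by 5.59 ± 0.34 after 4 h, and ADH1 by 1.84 ± 0.36 and 1.27. Fermentation and glycolysis genes fell in 9 of 21 cases after 4 h and 10 of 21 after 8 h, with 1 higher (0.253 and 0.654). Genes of abscisic acid, dehydration and cold rose in 8 of 24 cases (10 adjusted over the list alone) and 12 of 23, with 4 and 3 lower (0.777 and 0.575). RD29A rose by 2.76 ± 0.41 and 4.98 ± 0.36, and COR15B, a cold-regulated chloroplast protein gene, by 5.93 ± 0.66 after 8 h. The nuclease genes ENDO2 and RNS1, known from senescence and starvation, rose at least 43.6-fold and 95-fold after 8 h. DFR, an enzyme of anthocyanin synthesis, was at least 14.6-fold lower after 4 h, and LDOX of the same pathway at least 8.67-fold lower after 8 h. CASP1, a marker of the endodermis, fell by 2.81 and 2.74, while SCR rose by 1.55 after 4 h.

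Cell cycle genes were lower in 12 of 16 cases at 6 h after 8 h of anoxia (adjusted p = 0.43 with an estimated correlation), with KNOLLE at -2.18. Photosynthesis genes fell in 19 of 26 and 17 of 26 cases (19 and 18 adjusted over the list alone; 0.533 and 0.654), a list call that quantile normalization ended after 8 h (0.338). Darkness and starvation genes rose in 6 of 12 cases after 8 h (0.654) and 0 of 12 after 4 h by limma. At 6 h, 2059 genes rose and 2015 fell after 4 h, and 2420 rose and 2916 fell after 8 h. Both called 1355 higher and 1427 lower, against 243 and 293 if independent, and 13 oppositely. Within batches or slides that held both groups at least 99.7% of called genes had the same direction.

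**Figure D3:**
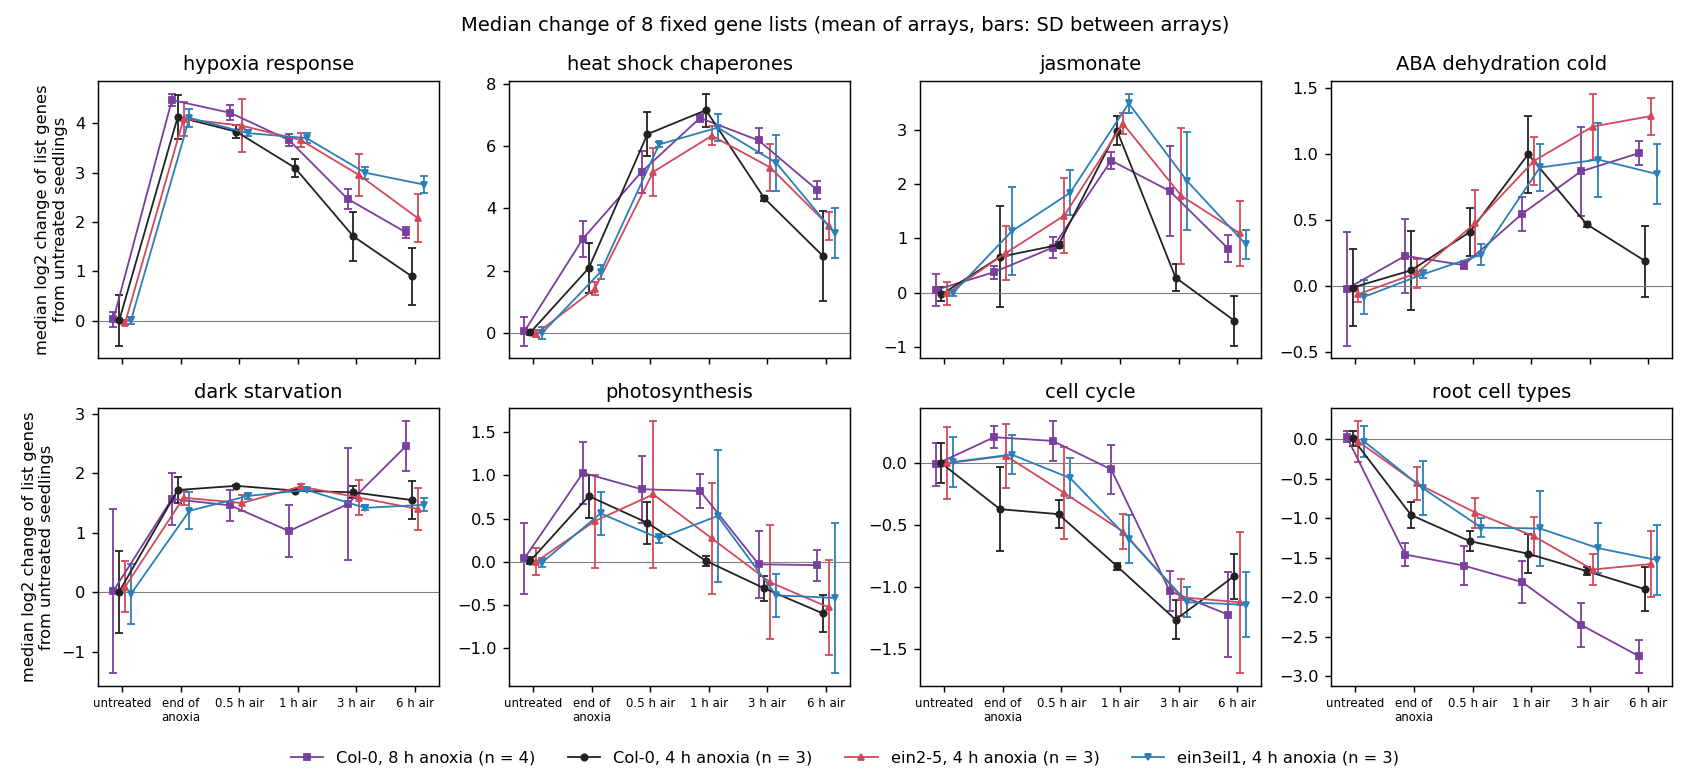
Lines join, for 8 gene lists and the 4 arms, the mean over arrays of the list's median log2 change from the untreated group of the same arm, and bars are SDs (n = 3 or 4 arrays). The hypoxia list stands at 1.71 ± 0.49 in Col-0, 2.95 ± 0.43 in ein2-5 and 3.00 ± 0.12 in ein3eil1 after 3 h of air. Some of its genes were already lower in untreated mutants than in untreated 4 h Col-0, so the starting levels differ between arms. The untreated 4 h Col-0 arrays were spread widely for some of these genes.

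How far transcripts had returned after 6 h of air was asked against untreated Col-0. ADH1 was still 37.2-fold higher after 4 h of anoxia (log2 5.22 ± 0.36, n = 3) and 43.6-fold after 8 h (5.45 ± 0.31, n = 4). PDC1 stood higher by 1.61 ± 0.41 and 4.18 ± 0.36, whereas SUS4 (0.48) was not called after 4 h and was higher by 1.52 after 8 h, a difference between experiments that was not tested. LBD41 stood at a log2 level of -1.40 ± 0.96 (SD) after 4 h and -1.21 ± 0.15 after 8 h, with untreated groups at -1.43 ± 2.16 and -4.69 ± 0.60, so its differences of 0.03 (not called) and 3.47 came with unlike untreated levels. Of 41 hypoxia genes 16 were higher and 3 lower after 4 h (17 higher adjusted over the list alone; adjusted p = 0.177 with an estimated correlation). After 8 h 28 were higher and 1 lower (0.0405). Small heat shock protein genes were far above untreated seedlings, HSP21 at least 174-fold after 4 h and 1090-fold after 8 h, and HSP17.4 at least 242-fold after 4 h. Chaperones were called higher in 15 of 24 (16 adjusted over the list alone) and 20 of 24 cases, with 1 lower each time (0.0676 and 0.0405). Darkness and starvation genes were higher in 7 of 12 (9 adjusted over the list alone) and 11 of 12 cases (0.177 and 0.0961).

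Root markers were lower than in untreated seedlings at 6 h, 10 of 12 after 4 h of anoxia and 9 of 11 after 8 h (adjusted p = 0.0676 and 0.0405 with an estimated correlation). CASP1 stood at -2.67 and -3.99, COBL9 at -3.07 and -5.38, and the root iron transporter gene IRT2 was at least 24.3-fold and 20.1-fold lower. Cell cycle genes were lower in 7 of 16 and 10 of 16 cases (0.177 and 0.122). Genes of abscisic acid, dehydration and cold were higher in 13 of 23 cases after 8 h, with 1 lower (0.0462), including COR15A by 5.06 and KIN2 by 3.01. Clock genes were higher in 7 of 15 cases and lower in 4 after 8 h (list adjusted p = 0.19; median 0.86, mean 0.13), against an untreated group with a deviating replicate 1.

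Limma called 693 genes higher and 1903 lower after 4 h of anoxia and 6 h of air, and 1490 higher and 2815 lower after 8 h, or 5182 in all without that replicate 1. Both experiments called 381 higher and 1180 lower, against 51.5 and 249.6 if independent, and 39 oppositely. On 2 slides 92.5% and 100% of called genes had the same direction after 8 h. Scanning batches gave 99.8% and 100% after 4 h.

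What the ethylene mutations change without treatment was asked against untreated Col-0. In ein2-5 the EIN2 transcript itself (AT5G03280) was lower by a log2 difference of -2.12 ± 0.32 (adjusted p = 1.68e-05, n = 3). In ein3eil1 EIN3 (AT3G20770) was lower by -1.60 ± 0.26 and EIL1 (AT2G27050) by -1.53 ± 0.30, the latter a call lost with slides as a fixed block. These probes may lie outside the lesions, so the values do not measure the proteins. Lower in both lines were the ethylene receptor gene ETR2 (-2.96 ± 0.29 and -3.15 ± 0.29), RAP2.3 (-2.72 ± 0.37 and -2.48), and the organ growth genes ARGOS (-3.73 ± 0.34 and -3.80) and ARL (-4.22 ± 0.29 and -4.38). ERS2, another receptor gene, was lower in ein2-5 (-1.46 ± 0.22). EBF2 was lower in both lines (-1.59 ± 0.35 and -2.29 ± 0.35), the former a call lost when either of 2 single arrays was left out. MRD1 was lower in ein3eil1 by -6.09 ± 0.77, and PER1 was at least 11.7-fold higher in ein2-5.

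Ethylene synthesis and signalling genes were called lower in 4 of 21 cases in ein2-5 and 6 of 21 in ein3eil1, counts that include the mutated genes EIN2, EIN3 and EIL1. Without the genes mutated in each line, 3 of 20 were lower in ein2-5 (adjusted p = 0.00421 with an estimated correlation) and 4 of 19 in ein3eil1 (4.9e-05). Ethylene response factors and markers were lower in 3 of 21 (8 adjusted over the list alone; 0.114 with an estimated correlation) and 5 of 21 (10 adjusted over the list alone; 0.065). In the hypoxia list 7 of 38 were lower in ein2-5 (9 adjusted over the list alone; 0.114) and 6 of 38 in ein3eil1 (8 adjusted over the list alone; 0.185). Its members LBD41 (-2.69 in ein2-5) and HB1 (-1.92 and -1.90) lost their calls without replicate 1 of untreated 4 h Col-0. That group was spread widely for LBD41 (mean -1.43, SD 2.16) and AT4G10270 (0.87, SD 2.06). Untreated 8 h Col-0 stood at -4.69 and -1.89, near untreated ein2-5 at -4.12 and -1.90. For such genes a raised 4 h Col-0 group and an effect of the mutations cannot be told apart. HB1 went the other way, at 1.56 in untreated 8 h Col-0, 1.90 in 4 h Col-0 and -0.02 in ein2-5.

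Limma called 47 genes higher and 100 lower in ein2-5, and 28 higher and 106 lower in ein3eil1. Without replicate 1 of untreated 4 h Col-0 the counts were 68 and 63, without replicate 2 they were 222 and 221, and without replicate 3 they were 75 and 72. In ein2-5 leaving out replicate 1 or 3 of the mutant gave 94. The lines share their Col-0 arrays: 18 genes were higher and 72 lower in both, and differences correlated across genes at 0.87, against 0.50 in 100 simulations with unchanged genes. Part of this overlap may come from the shared controls. The correlation alone does not tell, as it was 0.83 for the mutants' differences in the response to anoxia, where 0 genes were called in both lines. Within scanning batches 93.9% and 100% of called genes had the same direction in ein2-5, and 1 slide gave 100% in ein3eil1, for which 289 genes were called with slides as a fixed block.

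The response of the mutants to 4 h of anoxia was asked in the same way as in Col-0. In ein2-5 PDC1 rose by 6.69 ± 0.41 and ADH1 by 5.96 ± 0.36, and in ein3eil1 by 6.64 ± 0.41 and 5.26 ± 0.36 (n = 3). SUS4 rose by 5.78 and 5.70, LBD41 by 6.09 and 6.03, HB1 by 4.97 and 4.83, and ETR2 by 2.14 and 2.21. Hypoxia genes rose in 39 of 43 cases with 1 lower in ein2-5 and in 40 of 43 in ein3eil1 (adjusted p = 8.28e-06 and 5.89e-06 with an estimated correlation). Chaperones rose in 10 of 22 (12 adjusted over the list alone; 0.202) and 17 of 23 cases (19 adjusted over the list alone; 0.0794). Limma called 707 genes higher and 1592 lower in ein2-5, and 784 higher and 1352 lower in ein3eil1. Within slides at least 99.5% of called genes had the same direction.

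Tested as a difference from the response of Col-0, only EBF1 (-1.87 ± 0.33, adjusted p = 0.00723) was called in ein2-5 and only ARL (2.16 ± 0.40, adjusted p = 0.0322) in ein3eil1. EBF1 lost its call when any of 4 single arrays was left out, and ARL with any of 9. Limma gave 232 and 224 genes at an unadjusted p under 0.05. ADH1 differed by -1.10 ± 0.51 and -1.80 ± 0.51, PDC1 by -0.74 and -0.79 and LBD41 by 1.81 and 1.74, none of them called. The counts ranged up to 11 and 15 without replicate 2 of untreated 4 h Col-0.

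Whether the mutants depart from Col-0 in air was tested on the change from the end of anoxia. At 0.5 h limma called 0 genes in either line, with 130 in ein2-5 and 33 in ein3eil1 at an unadjusted p under 0.05. At 1 h it again called 0, with 532 and 1164. Those counts at 1 h were 25 and 3 without the 8 arrays of extreme gene-length trend, 7 and 1 with slides as a fixed block, 1 and 4 as a random block, and 1 and 2 with a replicate block. At 0.5 h ein2-5 had 5 without the 8 arrays, and ein3eil1 had 1 with a replicate block or without its replicate 2 at that time. The hypoxia list at 1 h had medians of 0.59 and 0.64 above Col-0 (adjusted p = 0.552 and 0.713 with an estimated correlation).

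After 3 h of air CYP94B3, which like CYP94C1 oxidises the jasmonate hormone, was higher in ein2-5 than in Col-0 by 5.30 ± 0.79 (adjusted p = 0.000165) and in ein3eil1 by 4.94 ± 0.79 (adjusted p = 0.00098, a call lost with slides as a fixed block). SRO5 was higher by 3.59 ± 0.72 and 3.49, calls lost when any of 4 and 9 single arrays was left out, and RBOHD by 1.81 in ein2-5, lost with any of 7. ARL was lower by -1.89 and -1.98, lost with any of 6 and 9. Of 43 hypoxia genes 3 were higher in ein2-5 (9 adjusted over the list alone; adjusted p = 0.103 with an estimated correlation) and 2 in ein3eil1 (16 adjusted over the list alone; 0.0302), with medians of 1.04 and 1.05. In ein2-5 0 of 24 chaperones were called over all genes (15 adjusted over the list alone; 0.106). Of 26 jasmonate genes 1 was called in each line (8 and 3 adjusted over the list alone; 0.157 and 0.22). Fermentation and glycolysis genes were called in 0 of 21 cases in either line (6 and 6 adjusted over the list alone; adjusted p = 0.157 and 0.22 with an estimated correlation).

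At 3 h limma called 22 genes higher and 5 lower in ein2-5, and 6 higher and 3 lower in ein3eil1. Leaving out 1 array moved the first count from 6, without replicate 1 of Col-0 at the end of anoxia, to 456 without replicate 2 of ein2-5 at 3 h, with 9 arrays moving it by over 1.5 times. The other ran from 1 without replicate 1 of Col-0 at 3 h to 21 without replicate 2 of ein3eil1 at 3 h, with 11 such arrays. Fitted on only the compared arrays both counts were 0, and with slides as a fixed block 431 and 0. The share of ein2-5 calls that were higher moved from 81.5% to 71.1% with quantile normalization, and that of ein3eil1 from 66.7% to 85.7% with median centring. In both scanning batches that held the groups of ein2-5, 100% of the 27 genes had the same direction, a share raised by calling them on these arrays among others. No slide or batch held those of ein3eil1.

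After 6 h of air hypoxia genes were higher in the mutants than in Col-0, relative to the end of anoxia. At that end HB1 stood at 6.33 in Col-0, 4.95 in ein2-5 and 4.83 in ein3eil1. PDC1 stood there at 4.69, 3.95 and 4.11, and HRE2 at -0.06, -0.86 and -0.68. Part of the differences may therefore lie in lower levels of the mutants at the end of anoxia. In ein3eil1 PDC1 was higher by 3.89 ± 0.58 (adjusted p = 6.75e-05), HRE2 by 4.30 ± 0.70 (adjusted p = 0.000419) and RNS1 by 4.05 ± 0.75. HB1 (2.84) lost its call without replicate 2 of Col-0 at 6 h or replicate 3 of ein3eil1 at 6 h, and NIP2;1 without the former. In ein2-5 HRE2 was higher by 3.07, lost when any of 7 arrays was left out, and PDC1 was not called (2.31, adjusted p = 0.0573). Of 43 hypoxia genes 14 were higher in ein3eil1 (24 adjusted over the list alone) with a median of 1.59 (adjusted p = 0.0041 with an estimated correlation). In ein2-5 the count was 4 (17 adjusted over the list alone) with a median of 1.30 (0.0418). Fermentation and glycolysis genes were higher in 2 of 21 cases in each line (7 and 8 adjusted over the list alone; 0.0615 and 0.0447). SUS1 in ein2-5 lost its call when any of 7 single arrays was left out. ALAAT1 lost its call with either of 2 in ein2-5 and any of 3 in ein3eil1. From the untreated group of their own arm, hypoxia genes stood at 0.90 ± 0.58 (SD, n = 3) in Col-0, 2.08 ± 0.48 in ein2-5 and 2.76 ± 0.17 in ein3eil1. Some of them were already lower in the untreated mutants than in untreated 4 h Col-0. Part of this gap may therefore lie in the starting levels. Untreated LBD41 stood at -1.43 ± 2.16 (SD), -4.12 and -4.18 in these arms, and at -4.69 in 8 h Col-0. Untreated PDC1 stood at -2.74, -2.74 and -2.53 in Col-0, ein2-5 and ein3eil1 of the 4 h arms.

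CYP94B3 was higher at 6 h in both lines as well (5.45 ± 0.79, adjusted p = 4.04e-05, and 4.78 ± 0.79, adjusted p = 0.000419). The expansin gene EXPA10 was higher by 3.20 ± 0.53 and 2.77 ± 0.53, and SRO5 by 3.97 ± 0.72 in ein2-5. UGT73C6, a flavonol glucosyltransferase gene, was called higher in ein3eil1, against Col-0 arrays not above background at 6 h, so no size is given. In ein2-5 the calls of EXPA10 and SRO5 were lost with slides as a fixed block. Genes of abscisic acid, dehydration and cold had medians of 0.93 and 0.74 (adjusted p = 0.0418 and 0.0447 with an estimated correlation) although 0 of 24 were called over all genes (6 and 3 adjusted over the list alone). Oxidative stress genes in ein3eil1 had a median of 0.72, with 1 of 26 called (4 adjusted over the list alone; 0.0447).

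At 6 h limma called 52 genes higher and 4 lower in ein2-5, and 60 higher and 2 lower in ein3eil1. The first count ran from 14 without replicate 3 to 258 without replicate 2 of ein2-5 at 6 h, and 9 single arrays moved it by over 1.5 times. The other ran from 16 without replicate 2 of Col-0 at 6 h to 102 without replicate 2 of Col-0 at the end of anoxia, with 6 such arrays. Fitted on only the compared arrays the counts were 6 and 5, and with slides as a fixed block 49 and 251. Both scanning batches that held the groups of ein2-5 gave the same direction for 100% of its 56 genes, which were called on these arrays among others. None held those of ein3eil1.

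Genes that rose in Col-0 after 8 h of anoxia (1497) or after its 1 h of air (1078) were followed as sets in the 4 h arms. The anoxia set stood at 1.00, 0.98 and 0.99 above untreated in Col-0, ein2-5 and ein3eil1 at the end of anoxia. After 3 h of air it stood at 0.09 ± 0.03 (SD, n = 3), 0.52 ± 0.25 and 0.43 ± 0.15, and after 6 h at -0.08 ± 0.10, 0.25 ± 0.14 and 0.26 ± 0.09. The median gene was higher in ein2-5 by 0.08 at 0.5 h and 0.34 at 1 h of air (adjusted p = 0.914 and 0.0272 with an estimated correlation), and in ein3eil1 by 0.10 and 0.36 (0.168 and 0.0837). It was higher in ein2-5 by 0.44 at 3 h and 0.38 at 6 h (adjusted p = 0.000871 and 0.0333 with an estimated correlation), and in ein3eil1 by 0.34 and 0.36 (0.00818 and 0.0286). At 0.5 and 1 h exact permutation of the genotype within each time gave two-sided p-values of 0.595 and 0.065 for ein2-5. For ein3eil1 they were 0.835 and 0.1. At 3 and 6 h this permutation gave 0.02 and 0.02 for ein2-5 and 0.055 and 0.005 for ein3eil1, the last the smallest that 400 relabelings allow. The set of 1 h of air was higher at those times by 0.64 and 0.45 in ein2-5 (0.00286 and 0.0484 with an estimated correlation) and by 0.49 and 0.29 in ein3eil1 (0.00965 and 0.257). Its exact permutation p-values were 0.075, 0.085, 0.14 and 0.18.

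Within the scanning batches that held ein2-5 and Col-0, the anoxia set was higher in ein2-5 by 0.14 and 0.38 at 3 h and by 0.10 and 0.50 at 6 h. The set of 1 h of air was higher by 0.22 and 0.47, and by 0.22 and 0.65. The differences of both mutants correlated across genes at 0.92 after 3 h and 0.90 after 6 h, against 0.50 in simulations of shared Col-0 arrays alone. For the response to anoxia the correlation was 0.83, with a covariance of 0.107 against 0.115 simulated and 0 genes called in both lines. A correlation above 0.50 thus does not by itself show a shared effect. After 3 and 6 h of air the covariance exceeded the simulated one by 0.156 and 0.217. At 6 h 27 genes were called higher in both lines, against 0.15 if independent. Part of that excess may come from the shared controls.

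**Figure D4:**
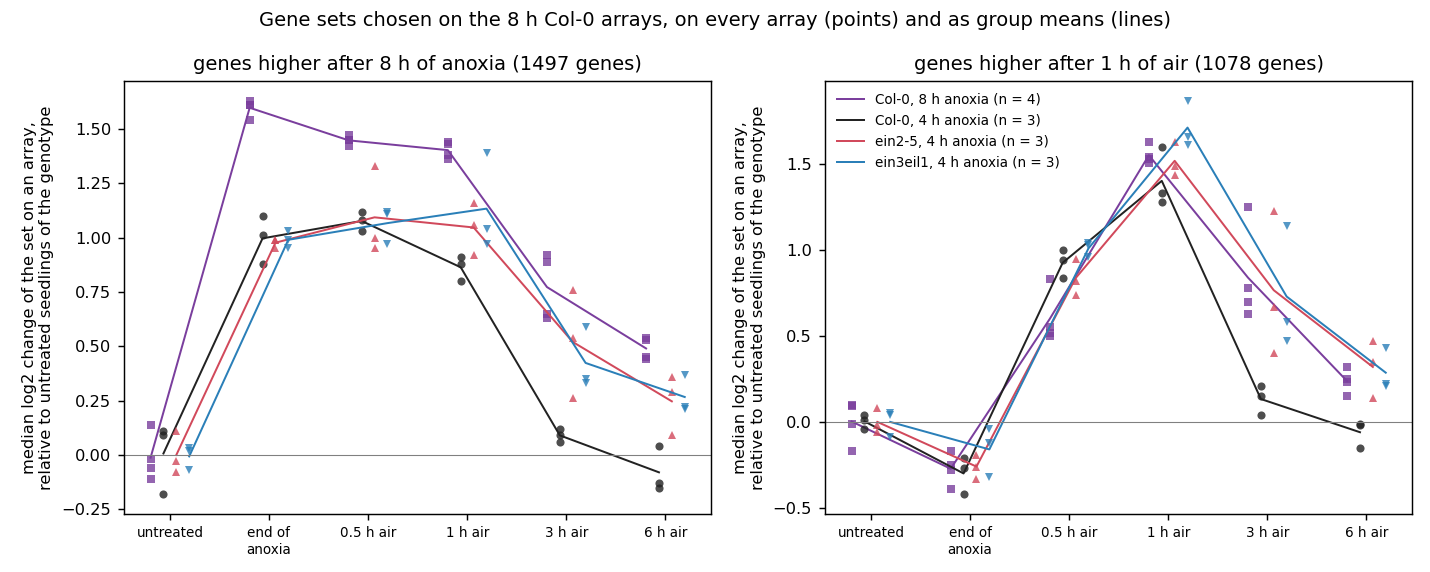
Points are the median log2 change of a gene set on single arrays from the untreated group of the same arm, and lines join group means (n = 4 for 8 h Col-0, 3 otherwise), for 1497 genes higher after 8 h of anoxia and 1078 genes higher after 1 h of air. At 3 h of air the anoxia set has a mean of 0.09 in Col-0, 0.52 in ein2-5 and 0.43 in ein3eil1.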

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

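Of the tests below, those of loss of ethylene signalling, of a stronger response to anoxia in the mutants and of harvest at another time of day were chosen only after the result was seen, as were the gene-length covariate and the random block for slides.

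In 132 comparisons of 4 arrays of 8 h Col-0, the gap of 1 array to its nearest neighbour exceeded the critical share of the range in 10, and chance gives about 1 in 20. Replicate 1 of the untreated group was high for HRE1 (0.958) and PCO1 (0.855) and low for RBOHD (0.937) and JAZ1 (0.834). EIN3 was low in replicate 3 at the end of anoxia (0.886). Replicate 1 at 0.5 h of air was low for ADH1 (0.853), EIN2 (0.945) and EBF2 (0.912). At 1 h of air PDC1 was low in replicate 1 (0.948) and PCO2 high in replicate 2 (0.851).

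That untreated replicate 1 also had most evening genes above and morning genes below the other 3 arrays, by a combined deviation of 6.91, against 6.53 as the largest of the other 77 arrays. The evening gene GI went the other way, with a difference of -1.13. A swap with another group of the 8 h experiment was argued against. The array correlated more closely with its own group than with any other group of that experiment, by 0.20. A swap with an untreated array of a 4 h arm was not tested. A gene-length trend was argued against too, as its slope lay -0.39 median absolute deviations from the mean of its group. Harvest at another time of day stays open as a candidate explanation, chosen after the values were seen.

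The 8 h and 4 h responses, of which no slide or scanning batch held all groups, differed at the end of anoxia in 136 genes, with the auxin and expansion list 0.70 higher after 8 h, and in their changes at 1 h of air in 108. Other random splits of the same arrays gave at least as many genes in 11 and 14 of 100 draws, so chance was not excluded. The highest other splits called 2021 and 2452 genes, which points to a structure of the samples.

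Mutants differed from Col-0 in 1 gene each at the end of anoxia, in 27 (ein2-5) and 9 (ein3eil1) at 3 h of air, and in 56 and 62 at 6 h. Chance was not excluded for any of these counts: 23, 22, 21, 15, 13 and 7 of 100 draws gave as many, and the highest others called 677, 180, 1143, 297, 2124 and 523 genes. Splits that call many times the real count point to a structure of the samples. At 0.5 and 1 h, where limma called 0 genes, all 100 draws must give as many in each line, so these draws decide nothing. The highest others there called 4279 and 1364 in ein2-5 and 649 and 627 in ein3eil1.

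Gene sets and lists differed between mutants and Col-0 as well. In ein2-5 the anoxia set was higher by 0.34 at 1 h, 0.44 at 3 h and 0.38 at 6 h, and the set of 1 h of air by 0.64 at 3 h and 0.45 at 6 h. In ein3eil1 the anoxia set was higher by 0.34 and 0.36 at 3 and 6 h, and the other by 0.49 at 3 h. At 6 h the hypoxia list was higher by 1.30 in ein2-5 and 1.59 in ein3eil1, and at 3 h by 1.05 in ein3eil1. Abscisic acid, dehydration and cold genes were higher by 0.93 and 0.74 at 6 h, and in ein3eil1 fermentation and glycolysis by 0.66 and oxidative stress by 0.72.

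Over both lines at 3 and 6 h of air, the anoxia set was higher by a mean of 0.36 (SE 0.11) and the set of 1 h of air by 0.42 (SE 0.13). With the gene-length slope as a covariate the shifts were 0.28 ± 0.10 and 0.36 ± 0.13, and with slides as a block 0.47 ± 0.13 and 0.62 ± 0.17, so neither trend removed them. The lowest values on leaving out 1 array were 0.32 ± 0.12 and 0.37 ± 0.11. A stronger response to anoxia was argued against, with a shift of -0.01 ± 0.13 at its end. The lower of both lines had 0.31 ± 0.13 and 0.35 ± 0.15, so slower return after loss of ethylene signalling may be an explanation. The lines share their Col-0 arrays, and no slide held all groups.

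Gene-length trends of arrays followed the scanner signal, with r = 0.91 and rho = 0.80 over 78 arrays (permutation p = 1e-04, the smallest possible), and r = 0.89 without the 2 farthest. Slides took up 64.7% of their variance (permutation p = 1e-04, the smallest possible). A technical source is therefore a candidate explanation of these trends, and no biological explanation was tested.

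Among splits of 2 groups, the design of 3 against 3 arrays makes too few for a share under 0.05. The real split was the 1 of 10 with as many genes in each of these comparisons. For Col-0 after 4 h of anoxia it called 2810 genes against 2 in the highest other, and then 634 against 2, 2517 against 0, 4037 against 1 and 4074 against 1 at 0.5, 1, 3 and 6 h of air, and 2596 against 9 for 6 h against untreated. Untreated mutants gave 147 against 33 and 134 against 12, and their anoxia 2299 against 14 and 2136 against 1.

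With 4 against 4 arrays not taken as paired by number, only 1 of 35 splits gave as many genes. This excludes chance only if numbers do not pair the arrays. That is uncertain, as same-number arrays of the 8 h arm correlated at 0.17 on average, against -0.05 for other numbers. With pairs, too few splits would remain for a share under 0.05. After 8 h of anoxia the counts were 4162 against 2298, and at 1, 3 and 6 h of air 1270 against 256, 4941 against 1159 and 5336 against 1258. The highest other split of the first grouped untreated replicate 1 with arrays from the end of anoxia. Numbers paired the arrays at 0.5 h of air and for 6 h against untreated, where the 8 splits that part all pairs are too few for a share under 0.05. The real splits called 427 and 4305 genes, against at most 14 and 2067 in the others of the 8, and 65 and 2965 in splits that leave pairs together.

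Probes without a gene in the reference, which the comparisons do not use, changed too. After 4 h of anoxia 696 of 4077 were called, 459 higher and 237 lower, and after 8 h 933 of 3113, 649 higher and 284 lower.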

How the results depend on the processing

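Tests with the gene-length covariate, without the 8 arrays of extreme length trend and with slides as a random block were chosen only after the result was seen. The cause was not tested where a result changed.

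The deposited values gave the same call for all 448 list tests and all 1433 named gene tests. Of the list tests 441 kept direction and side of the threshold with median centring, 407 with quantile normalization, 404 with normexp background, 433 with the mean over probes, 435 with a strict filter and 443 with a replicate block. With an estimated correlation 26 of 199 list calls held, and 8 of 25 set calls.

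Normexp background lowered most counts. They were 1270 and 2368 after 4 and 8 h of anoxia, 385, 1382, 2362 and 2354 at 0.5, 1, 3 and 6 h of air after 4 h, 182, 736, 3122 and 3480 after 8 h, and 1500 for 6 h of air against untreated after 4 h. Differences between experiments fell to 21 at the end of anoxia and 19 at 1 h. Mutants gave 49 (ein2-5) and 45 (ein3eil1) untreated, 1069 and 1045 for anoxia, 0 for the anoxia difference of ein3eil1, 7 and 5 at 3 h, and 36 at 6 h in ein3eil1. The 4 h and 8 h experiments shared 1021 calls after anoxia, against 2163. With it the set lowered at 1 h of air reversed at 6 h in ein2-5 (adjusted p = 0.0239) and ein3eil1 (0.0463), and so did SCPL43 at 0.5 h (0.24) and ACS4 at 6 h (-0.33) after 4 h, and HEI10 (0.31) and IQD12 (0.45) at 6 h in ein2-5.

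Quantile normalization gave 222 genes for the 8 h against 4 h difference, 2 for the anoxia difference of ein2-5 and 45 for ein2-5 at 3 h. Median centring gave 0 for the anoxia difference of ein3eil1. The mean over probes gave 0 for that of ein2-5. No filter gave 2 for that of ein3eil1 and 3 for ein3eil1 at 3 h. A strict filter gave 84 for 8 h against 4 h and 33 for ein2-5 at 6 h, with fewer genes tested.

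Fitting only the compared arrays gave 57 for 8 h against 4 h, 0 and 0 for the anoxia differences of ein2-5 and ein3eil1, 0 and 0 at 3 h, and 6 and 5 at 6 h.

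With a replicate block, whose numbers do not pair the arrays of these comparisons, the counts were 486 for 8 h against 4 h and 368 at 1 h of air. Untreated mutants gave 245 and 259, the anoxia difference of ein2-5 2, ein3eil1 at 0.5 h 1, both lines at 1 h 1 and 2, at 3 h 188 and 36, and at 6 h 205 and 161. As a hint of what numbers mean, arrays of the same number correlated at a mean of 0.17 (8 h) and 0.28 (4 h), against -0.05 and -0.14 for other numbers, but pairs of the 8 h against 4 h difference ran from -0.27 to 0.49.

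With slides as a fixed block 322 genes were called for 8 h against 4 h, 487 at 1 h of air, 289 in untreated ein3eil1 and 2 for its anoxia difference, 7 and 1 in ein2-5 and ein3eil1 at 1 h, 431 and 0 at 3 h, and 251 in ein3eil1 at 6 h. As a random block they gave 521, 467, 244 and 312 untreated, 2 for the anoxia difference of ein2-5, 1 and 4 at 1 h, 462 and 74 at 3 h, and 151 and 177 at 6 h.

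The gene-length covariate gave 487 for 8 h against 4 h, 242 and 252 in untreated mutants, 2 for the anoxia difference of ein2-5, and 126 and 32 at 3 h. It reversed the photosynthesis list at 6 h in ein2-5 (adjusted p = 0.0376) and ein3eil1 (0.0046), and the set lowered at 1 h of air in ein3eil1 at 1 h (0.043). Without the 8 arrays of extreme trend the counts were 675 for 8 h against 4 h, 599 at 1 h, 4 and 0 for the anoxia differences, 5 in ein2-5 at 0.5 h, 25 and 3 at 1 h, 1525 and 389 at 3 h, and 290 in ein2-5 at 6 h.

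Leaving out each array in turn kept all counts of 2 Col-0 groups within 1.5 times. Ranges of the others were 51 (without untreated 4 h replicate 1) to 439 (untreated 8 h replicate 1) for 8 h against 4 h, and 17 (4 h at 1 h of air, replicate 2) to 174 (8 h end of anoxia, replicate 3) at 1 h. They were 68 to 222 and 63 to 221 in untreated ein2-5 and ein3eil1 (without untreated 4 h Col-0 replicates 1 and 2), 0 to 11 and 0 to 15 for the anoxia differences, and 0 to 1 in ein3eil1 at 0.5 h. At 3 h they were 6 to 456 and 1 to 21, and at 6 h 14 to 258 and 16 to 102. Without Col-0 replicate 3 at the end of anoxia, the jasmonate list of ein3eil1 at 0.5 h reversed (adjusted p = 0.000963, in a range of 5.85e-12 to 0.275 over the arrays left out in turn). Signal over background limits genes near the floor, for which only bounds of folds are given.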

Other observations

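Gene families were chosen only after the result was seen, and so were their tests.

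Of the auxin-induced SAUR genes, 1 of 14 rose and 7 fell after 4 h of anoxia, with a median of -1.23, and after 8 h 9 of 13 rose and 3 fell, with a median of 1.85, and neither sign changed under normexp background, quantile normalization or median centring. The difference was called for 7 of 14 genes, with a median of 2.62 that stayed positive under the same scalings (adjusted p = 0.0771 with an estimated correlation). At 1 h of air after 4 h 10 of 14 rose, with a median of 1.97. SAUR68 differed by 2.64 ± 0.62 between experiments, which also differed in the clock genes of untreated seedlings. In the xyloglucan-modifying XTH family 15 of 25 genes were lower and 5 higher after 8 h of anoxia and 6 h of air than in untreated seedlings (adjusted p = 0.758 with an estimated correlation). XTH14 stood at -4.62 ± 0.29, XTH26 at -3.94 ± 0.59 and XTH21 at -3.73 ± 0.33, while XTH11 stood at 2.98 ± 0.42.

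WRKY transcription factor genes rose in 16 of 50 cases and fell in 4 after 8 h of anoxia (adjusted p = 0.546 with an estimated correlation). WRKY25 stood at 2.75 ± 0.34 and WRKY60 at -1.75. Calmodulin-like genes CML37 and CML23 rose by 5.50 ± 0.80 and 3.71 ± 0.26 at 0.5 h of air after 4 h, and by 4.65 ± 0.69 and 2.64 ± 0.22 after 8 h. Among 51 UGT glycosyltransferase genes 18 rose at 3 h of air after 4 h (adjusted p = 0.296 with an estimated correlation). All 13 light-harvesting genes fell at that time, but only 3 with quantile normalization.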
